A study of Gallus gallus with 20 samples.

How the data were processed

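Liver RNA of Guangxi Ma hens, a Chinese local chicken breed, was profiled by RNA sequencing of libraries enriched for mRNA, per the labels' protocols. The 20 libraries formed 5 groups of 4: week 32, week 50 with high laying, week 50 with low laying, week 72 with high laying and week 72 with low laying. The group and replicate number of each library came from its title. The characteristics of the week 32 libraries give high laying while the design text names no laying class at that age, so the week 32 group is called by its age alone. The labels do not say that the 4 libraries of a group came from separate hens, so p-values here measure only the spread between these samples, which may be technical.

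The authors deposited one table of TPM, a transcript abundance relative to all transcripts of a library, for 21749 genes, and the values of each library were not whole numbers. The submitters' processing notes name the chicken genome build GRCg7b. The aligner, the counting tool, the annotation release and any filter are not given in the sources used here. TPM divides by transcript length and scales each library to a fixed total, so it keeps no absolute sequencing depth. The listed genes of a library summed to between 764047 and 852815 TPM, that is 76.4% to 85.3% of the fixed total, and what holds the remainder is not given in the sources used here. None of the 29 symbols of the mitochondrially encoded list was in the table. Among 5342 low genes, 77.4% of 65903 values lay within 2% of a whole multiple of the gene's smallest value once a factor per library had been fitted, against 11.5% when the values were scaled at random and fitted alike. The smallest values themselves and large multiples were left out. From these steps the worth of 1 read in a library ranged from 0.890 to 1.09 relative to the others, and the absolute depth and counting error are unknown. A count model was not used for this reason.

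Symbols were matched to a RefSeq gene table of GRCg7b, which gave gene identifiers, positions and biotypes for 20888 of the 21749 genes while 861 did not match. Genes with at least 1 TPM in at least 4 libraries were tested, which left 12808. Differences were computed on log2(TPM + 1), a scale that understates the change of low genes. One linear model with a mean per group was fitted to all 20 libraries with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, 15 residual degrees of freedom). Each p-value was two-sided and adjusted over genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Errors of log2 differences are standard errors (SE) of this fit, and errors of group means are standard deviations (SD) over 4 libraries. The fit takes a single variance per gene over all groups, so a wide spread in any group raises the SE of every comparison. The 10 comparisons were high against low laying at each age, their mean, their difference between ages, each later group against week 32, and week 72 against week 50 within each laying class.

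Before the data were examined, 20 pathway lists and 12 cell type marker lists for liver were fixed, and 29 of them had at least 5 tested members. Each was tested with camera in limma at a preset correlation between genes of 0.01, adjusted over lists within a comparison. Camera with a correlation estimated from the data and fry, which asks whether the members of a list move one way without reference to other genes, were run beside it. Members were also tested with an adjustment over the list alone, and the mean of the members per library was compared between groups of 4 by an exact two-sided permutation test, which cannot give a p under 0.0286. Exact permutation p-values are given without adjustment over lists unless stated. Of 290 camera tests, 97 passed at the preset correlation and 2 with the estimated correlation. The estimated correlation was under the preset value for hepatocyte (-0.00116) and adipocyte markers (0.00832) and over it for the other lists tested, for which the preset value is lenient.

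The genes named were chosen by a rule fixed in advance: up to 10 called genes per direction with a symbol whose 4 libraries in one group did not overlap those of the other, the 3 genes with the smallest unadjusted p in a direction without such a call, the yolk precursor list, and up to 4 members of each other list with the smallest p. LOC107049678 was named outside this rule because it was called, and TCN2, FAM20CL, WFDC8 and ENPP7 were chosen after their values were seen. The values of some single genes that the rule selects are not reported here. The vitellogenins, the globins, the immunoglobulin light chain gene IGLL1 and THRSPB belong to families of similar genes, and their values are uncertain as far as the counting split reads between copies.

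The fit was tested on simulated data with known changes in 12808 genes. In the week 50 comparison of high and low laying, 52% of genes changed by 1 log2 unit, 88% of those changed by 2, and 100% of those changed by 4 or 6 were recovered, and 6.08% of the calls were false. In the comparison of low laying at weeks 72 and 50 the shares were 52%, 90% and 100%, with 4.47% false calls. Genes were simulated as independent, with the same spread in every group. The shares need not hold where genes are correlated or a group is spread more widely. In the data, VTG1 was not called at a log2 difference of 6.88 in week 72 high against low. The alternatives tried were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-ratio scaling, a replicate block, array weights, a minimum log2 difference of 1, fits with only the groups compared, and leaving out each library in turn. Leaving out the 3 libraries least like the others was added after seeing the data, as were counts of list members under each alternative and counts of lists under alternatives other than the replicate block, the estimated correlation and fry. Random or complete regroupings of the libraries gave the results that chance assignment of labels can produce. Correlations, regroupings of single values and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.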

Results

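Liver transcripts of Guangxi Ma hens were measured in 20 libraries, 4 in each of 5 groups that differ in age and laying performance: week 32, week 50 high, week 50 low, week 72 high and week 72 low. The series addresses genes related to yolk precursor synthesis in livers of hens with different laying rates. The table listed 21749 genes, of which between 17155 and 18005 were above 0 in a library, and 12808 were tested. Read depth cannot be taken from TPM, and the listed genes summed to between 764047 and 852815 TPM per library. The 10 genes with the highest values in a library held 13.9% to 29.1% of its listed total. Spearman correlations between libraries over the tested genes ranged from 0.898 to 0.965 in 190 pairs, and the first principal components held 16.9% and 13.3% of the variance. Week 50 high replicate 1, week 50 low replicate 3 and week 72 low replicate 2 were least like the others, with median correlations of 0.928, 0.923 and 0.923 and scores on the second component of -33.8, -53.5 and -44.4. Their deviations from the mean of all libraries correlated with the genomic span of genes with Spearman rho = -0.304, -0.216 and -0.154. Week 50 low replicate 4 had -0.164, and the highest value was 0.288, in week 32 replicate 1. The reason for this spread was not tested.

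The first question was how high and low layers differed at week 72. Vitellogenin transcripts, which encode the main yolk proteins, were lower in 3 of the 4 low libraries. VTG2 (chromosome 8, 16204330 to 16225309, GRCg7b) had 14215 ± 2081 TPM in high layers (SD, n = 4) and 725, 95.1, 13572 and 241 TPM in low replicates 1 to 4. VTG1 (chromosome 8, 18326424 to 18369074) had 6761 ± 2126 TPM in high layers and 48.0, 0.443, 7371 and 17.3 TPM in the low libraries. VTG3 (chromosome 8, 16254240 to 16275339) had 2115 ± 387 TPM against 23.1, 13.1, 2230 and 8.54 TPM. APOV1, the apolipoprotein of yolk-targeted lipoprotein particles (chromosome 1, 83462896 to 83465817), had 50828 ± 14969 TPM against 1787, 4838, 46760 and 199 TPM.

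**Figure D1:**
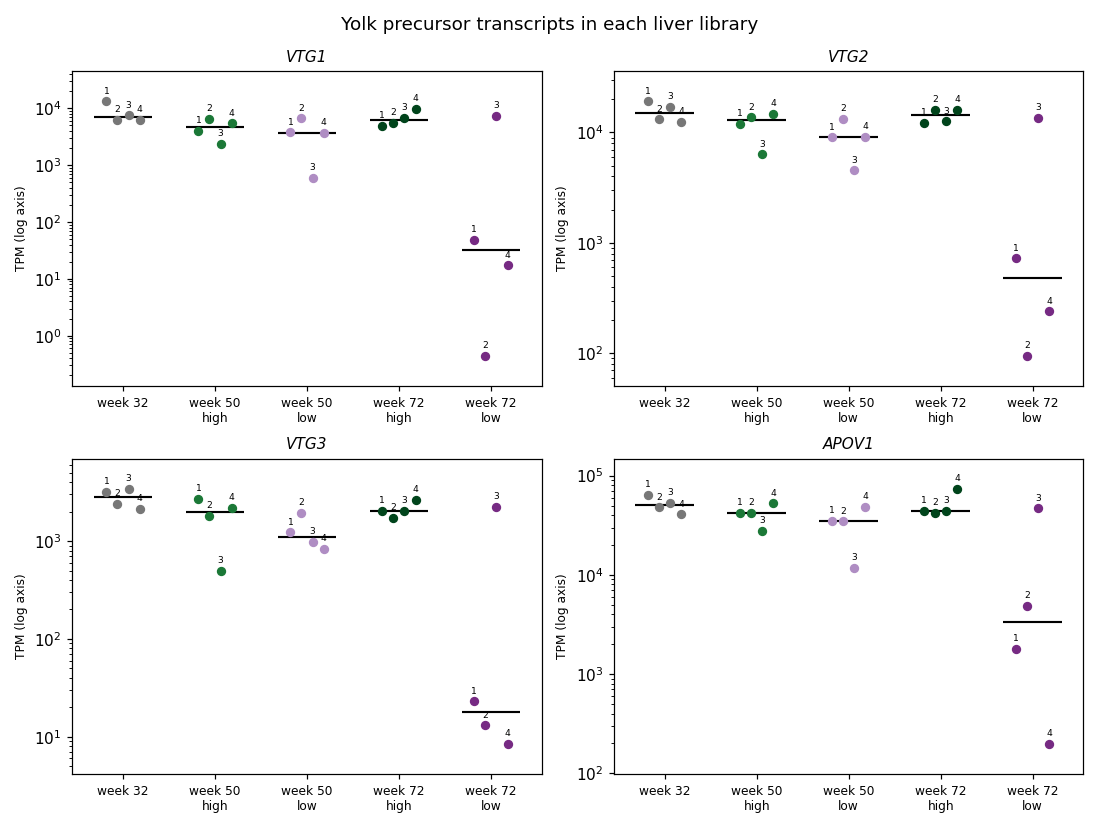
TPM of VTG1, VTG2, VTG3 and APOV1 in each of the 20 libraries on a log axis, by group, with bars at group medians and numbers giving the replicate. In week 72 low, replicate 3 lies at 13572 TPM of VTG2 and replicate 2 at 95.1 TPM.

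With all libraries, the high minus low log2 differences were 6.88 ± 1.53 for VTG1, 4.35 ± 0.92 for VTG2, 5.33 ± 1.09 for VTG3, 4.04 ± 0.98 for APOV1 and 3.38 ± 0.92 for the riboflavin-binding protein gene RBP (SE, 4 libraries per group). These 5 of the 15 yolk precursor members passed adjusted over the list alone, and 0 passed over all genes with limma, where VTG3 had an adjusted p = 0.166. APOB, the structural protein of lipoprotein particles, differed by 1.68 ± 0.72, and MTTP, which loads lipid onto it, by 0.05 ± 0.31, TF by 0.15 ± 0.31 and APOA1 by -0.95 ± 0.43, none of them passing. APOA4 (0.29 ± 0.74), APOA5 (-0.18 ± 0.35), APOC3 (-0.48 ± 0.48), BTD (0.39 ± 0.25), RBP4 (0.21 ± 0.35) and TTR (-0.32 ± 0.40) did not pass either. The list passed camera as higher (adjusted p = 0.000363, median 0.29), with adjusted p = 0.144 with an estimated correlation and an exact permutation p = 0.0857 for its mean.

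Cholesterol synthesis transcripts were higher in high layers at week 72: 17 of 20 members passed adjusted over the list alone and 0 over all genes with limma. NSDHL differed by 2.13 ± 0.46, SQLE by 3.16 ± 0.71 and DHCR7 by 2.33 ± 0.53. As with vitellogenin, 3 of the 4 low libraries carried the difference: the mean log2(TPM + 1) of the list was 4.60, 4.20, 6.50 and 4.81 in low replicates 1 to 4 and 6.50 ± 0.31 in high layers (SD, n = 4). The list passed camera (adjusted p = 1.97e-24, median 1.33), with adjusted p = 0.109 with an estimated correlation and an exact permutation p = 0.0857. In the fatty acid and triglyceride synthesis list 5 of 32 members passed as higher over the list alone, among them the desaturases SCD (3.42 ± 0.93) and FADS2 (1.51 ± 0.37) and the elongase ELOVL2 (2.47 ± 0.60), and camera gave an adjusted p = 1.87e-05 (adjusted p = 0.144 with an estimated correlation). That count was 0 without week 72 low replicate 1, 9 without replicate 3 and 3 without the 3 libraries least like the others. In the lipoprotein handling list, CETP (-2.50 ± 0.69) was lower and APOV1 higher over the list alone. LCAT differed by -1.36 ± 0.51 and LPL by -1.71 ± 0.66.

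Cell cycle (median 0.43) and interferon response (0.32) also passed camera as higher and extracellular matrix and stellate cell (-0.12) and endothelial (-0.14) markers as lower, with adjusted p = 0.76, 0.784, 0.687 and 0.564 with an estimated correlation. Camera called 11 lists, of which 0 held with an estimated correlation. Limma called 1 of 12808 genes over all genes, LOC107049678, a long non-coding RNA (chromosome 15, 20789 to 22557), which rose by 1.79 ± 0.27 with an adjusted p = 0.0348. It had 4.14 ± 1.16 TPM in high and 0.514 ± 0.468 TPM in low layers, and all 4 high libraries (2.98 to 5.35 TPM) lay above all 4 low ones (0 to 1.06 TPM). Among symbol-named genes the smallest p as lower were ST6GALNAC6 (-0.9999 ± 0.20), BHLHE22 (-1.25 ± 0.32) and RTN4RL2 (-0.96 ± 0.24), none called. TCN2 (2.31 ± 0.47), FAM20CL (5.41 ± 1.14), WFDC8 (2.30 ± 0.45) and ENPP7 (2.66 ± 0.47), chosen after their values were seen, were not called. At an unadjusted p under 0.05, 467 genes were higher and 208 lower, and 466 and 354 after median-ratio scaling. The call was lost, leaving 0 genes, without any 1 of the 4 week 72 high libraries or without week 72 low replicate 1 or 2, and also without the 3 libraries least like the others. It was also lost with the replicate block (adjusted p = 0.113), a pseudocount of 0.1 (0.195), no filter (0.0717) and only the groups compared in the fit (0.438), and a filter of 5 TPM left the gene out. Without week 72 low replicate 3, 63 genes passed, 59 higher and 4 lower, with VTG1 at 9.23 ± 0.87 and VTG3 at 7.14 ± 0.45. That library had VTG1 at 109% and VTG2 at 95.5% of the week 72 high mean. Leaving it out was bound to widen the yolk differences, so the counts without it, here and below, are no separate evidence for them.

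At week 50, yolk precursors differed little between high and low layers relative to their spread. VTG2 had 11700 ± 3749 TPM in high and 9009 ± 3577 TPM in low layers (SD, n = 4), a log2 difference of 0.41 ± 0.92. VTG1 differed by 0.66 ± 1.53, VTG3 by 0.35 ± 1.09, APOV1 by 0.47 ± 0.98 and APOB by 0.11 ± 0.72. These SE pool all groups and do not measure the spread at week 50 alone. The SD of the yolk precursor list score was 0.26 in week 50 high and 0.43 in week 50 low, but 1.16 in week 72 low. B or plasma cell markers were lower in high layers, with POU2AF1, a B cell coactivator (-1.41 ± 0.40), and MZB1, a plasma cell chaperone (-2.03 ± 0.77), passing adjusted over the list alone (2 of 6) and 0 over all genes. Camera gave an adjusted p = 2.41e-07 and a median of -1.72, with adjusted p = 0.219 with an estimated correlation and an exact permutation p = 0.286. The count of 2 was 1 without week 50 high replicate 1 or 3, 0 without week 50 high replicate 2 or week 50 low replicate 1 or 3, and 5 without week 50 low replicate 2 or 4. Erythroid markers were lower (median -1.05, camera adjusted p = 1.05e-06, adjusted p = 0.219 with an estimated correlation, exact permutation p = 0.143), with HBBA, a beta globin, at 92.8 ± 23.4 TPM in high layers and 207, 58.6, 1598 and 252 TPM in the low libraries.

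Interferon response (median -0.43) and cholesterol synthesis (-0.21) were lower and T or NK cell markers (0.34) higher by camera at week 50, with adjusted p = 1.16e-07, 0.000122 and 0.0078, and adjusted p = 0.78 for each with an estimated correlation. The smallest p belonged to the phosphatase subunit gene PPP2CA (0.80 ± 0.18), SH3BP4 (0.85 ± 0.20) and ABLIM1 (1.02 ± 0.25) as higher, and to LRRC20 (-1.11 ± 0.29), the tRNA gene TRNAG-GCC_4 (-1.60 ± 0.45) and POU2AF1 as lower. Limma called 0 of 12808 genes, and 380 had an unadjusted p under 0.05, 255 higher and 125 lower, where 640.4 are expected by chance. After median-ratio scaling 190 were higher and 203 lower.

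In the mean over both ages, VTG1 was higher in high layers by 3.77 ± 1.08, VTG2 by 2.38 ± 0.65, VTG3 by 2.84 ± 0.77 and APOV1 by 2.26 ± 0.69 (SE, 8 libraries per class), and these 4 of 15 yolk members passed adjusted over the list alone, none over all genes. These means rest on week 72, where the differences were 6.88, 4.35, 5.33 and 4.04. At week 50 they were 0.66 ± 1.53, 0.41 ± 0.92, 0.35 ± 1.09 and 0.47 ± 0.98, and 0 of 15 yolk members passed over the list alone. Camera gave the list an adjusted p = 0.0362 (median 0.19, adjusted p = 0.592 with an estimated correlation). The call was lost with the replicate block (adjusted p = 0.0594), with only the groups compared in the fit (0.0576), without the 3 libraries least like the others (0.343), and without week 50 high replicate 1 or 2, week 50 low replicate 2 or 3, week 72 high replicate 1 or 4, or week 72 low replicate 2. The cholesterol synthesis list went opposite ways at the 2 ages. At week 50, 18 of 20 members had a negative high minus low difference (median -0.21), and at week 72 all 20 had a positive one (median 1.33). In the mean over both ages, 4 of 20 members passed as higher over the list alone, among them DHCR7 (1.12 ± 0.38), NSDHL (0.95 ± 0.32) and SQLE (1.48 ± 0.50). Camera gave this mean an adjusted p = 2.56e-06, and adjusted p = 0.592 with an estimated correlation. That count was 0 without week 50 high replicate 2 or 4, week 50 low replicate 1, 3 or 4, week 72 high replicate 1, 2 or 3, or week 72 low replicate 1, 2 or 4. It was 6 without week 50 low replicate 2, 10 without week 50 high replicate 3, 13 without week 72 low replicate 3 and 0 without the 3 libraries least like the others. FABP1, a fatty acid carrier (0.95 ± 0.24), was higher and CETP (-1.80 ± 0.49) lower over their lists alone. Extracellular matrix and stellate cell markers passed camera as lower (adjusted p = 0.0411, adjusted p = 0.741 with an estimated correlation) with a mean of -0.07 and a median of 0.00, which was -0.04 after median-ratio scaling.

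Limma called 1 gene over both ages, LOC107049678, which rose by 1.31 ± 0.19 (adjusted p = 0.0225). ISYNA1 (-0.97 ± 0.22), RBPMS (-1.04 ± 0.25) and CSTA (-0.85 ± 0.21) had the smallest p as lower. Camera called 12 lists, 0 with an estimated correlation. At an unadjusted p under 0.05, 599 genes were higher and 225 lower, and 497 and 456 after median-ratio scaling. No gene was called (0) without week 50 high replicate 2, week 50 low replicate 2, 3 or 4, week 72 high replicate 1 or 3, or week 72 low replicate 1 or 2. The number was 2 without week 50 high replicate 3 or 4 or week 50 low replicate 1, 33 without week 72 low replicate 3 and 0 without the 3 libraries least like the others. LOC107049678 was not called with the replicate block (adjusted p = 0.0775), a pseudocount of 0.1 (0.186) or only the groups compared in the fit (0.0876), and a filter of 5 TPM left it out.

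The test of whether the laying difference itself differed between ages was largest for cholesterol synthesis, whose week 72 minus week 50 difference had a median of 2.08. MVD, which makes the isoprenoid building block, differed by 2.09 ± 0.52 and NSDHL by 2.35 ± 0.64, and 14 of 20 members passed adjusted over the list alone, 0 over all genes. The count was 9 without the 3 libraries least like the others, an alternative added after seeing the data. Camera gave the list an adjusted p = 2.21e-33, and this call held with an estimated correlation (adjusted p = 0.0328). The contrast contains the difference between week 72 low and week 50 low, which gave the other list call that held. The 2 calls share those libraries and are not independent results. In the yolk list VTG1 (6.22 ± 2.17), VTG2 (3.94 ± 1.30) and VTG3 (4.98 ± 1.54) passed over the list alone, 3 of 15, with a camera adjusted p = 5.61e-05 and adjusted p = 0.0951 with an estimated correlation. Interferon response (median 0.72) and fatty acid and triglyceride synthesis (0.50) also passed camera as higher and endothelial markers (-0.29) as lower, with adjusted p = 0.606, 0.0615 and 0.169 with an estimated correlation. Limma called 0 of 12808 genes and 304 had an unadjusted p under 0.05. ZDHHC23 (1.03 ± 0.28) was higher and ST6GALNAC6 (-1.02 ± 0.29), PPP2CA (-0.89 ± 0.25) and CD28 (-1.70 ± 0.50) lower among those with the smallest p. Without week 72 low replicate 3, 18 genes passed, all higher.

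The laying differences at both ages shared no libraries, and across genes, which are not independent replicates, they correlated with Pearson r = 0.199 and Spearman rho = 0.232, with the same sign in 59.4% of genes. Random exchange of high and low labels within ages gave r from -0.303 to 0.276 in 100 draws, and 19 draws lay as far out for r, 22 for rho and 28 for the share of signs. At an unadjusted p under 0.05, 37 genes were higher in high layers at both ages and 12 lower, where independent lists give 9.30 and 2.03. Those expected numbers take genes as independent, and label exchange was not run for these counts. The excess therefore cannot be told from chance. The number of genes called at both ages with limma was 0.

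In low layers, week 72 differed from week 50 in cholesterol synthesis above all other lists by camera. FDPS (chromosome 25, 2115433 to 2119023) fell by 2.79 ± 0.49, from 212 ± 63.4 to 40.7 ± 43.0 TPM (SD, n = 4), NSDHL (chromosome 4, 11231433 to 11241992) by 2.60 ± 0.46 and MVD (chromosome 11, 18069487 to 18072385) by 2.28 ± 0.37. DHDH, a dihydrodiol dehydrogenase (chromosome 31, 1295109 to 1299652), fell by 1.76 ± 0.31. They were among the 5 genes called by limma (adjusted p = 0.0468), and in each of the 5 all 4 week 72 low libraries lay below all 4 week 50 low ones. Of 20 cholesterol synthesis members 18 were lower adjusted over the list alone and 4 over all genes. Camera gave an adjusted p = 1.12e-33 (median -2.32), which held with an estimated correlation (adjusted p = 0.0316), and the exact permutation p of the list mean was 0.0286, the smallest possible.

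**Figure D2:**
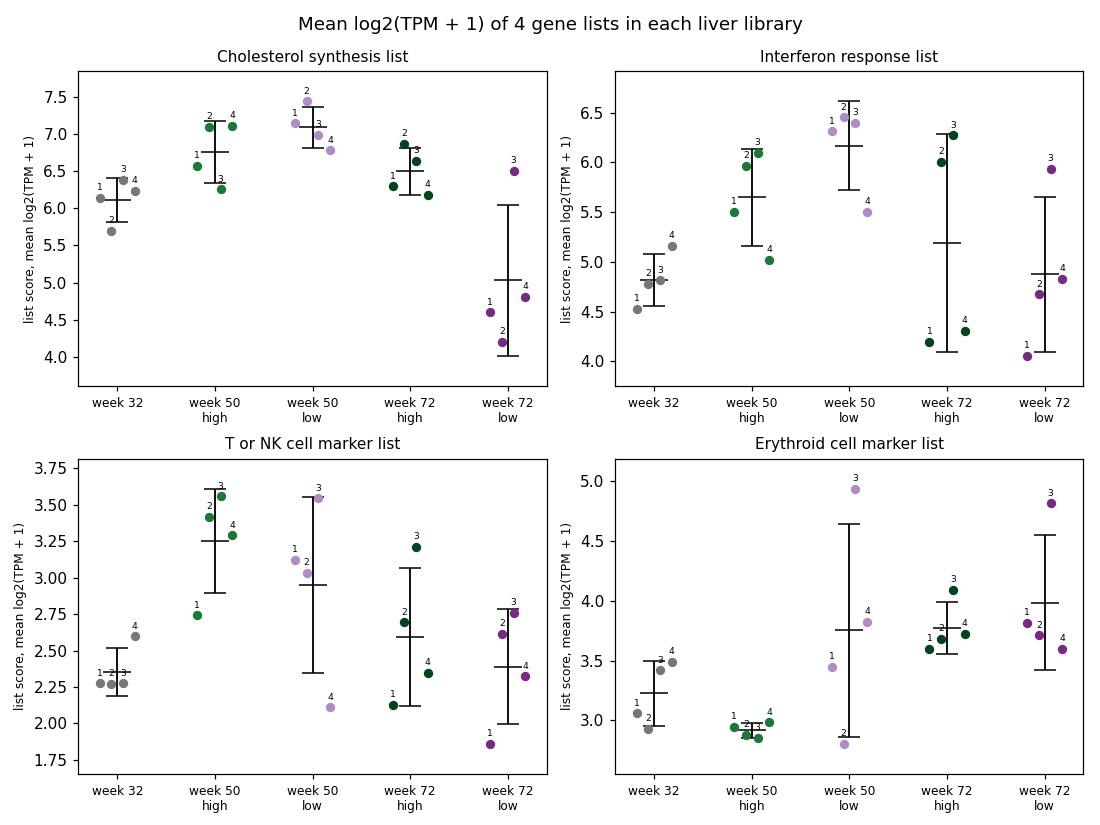
Mean log2(TPM + 1) over the members of the cholesterol synthesis, interferon response, T or NK cell and erythroid cell lists in each of the 20 libraries, by group, with bars at the mean ± SD of 4 libraries. The cholesterol synthesis score was 7.09 ± 0.28 in week 50 low and 5.03 ± 1.01 in week 72 low.

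Cell cycle members were lower in week 72 low, 27 of 37 adjusted over the list alone and 0 over all genes, with the mitotic kinase PLK1 at -2.03 ± 0.45, CCNB3 at -2.04 ± 0.47 and TOP2A at -2.10 ± 0.50. Camera gave an adjusted p = 6.46e-24 (median -1.05), with adjusted p = 0.165 with an estimated correlation. Interferon response was lower for 18 of 35 members over the list alone, among them CMPK2 (-2.25 ± 0.60), HELZ2 (-1.27 ± 0.34) and IRF7 (-0.99 ± 0.30), with a camera adjusted p = 8.41e-17, adjusted p = 0.202 with an estimated correlation and an exact permutation p = 0.0571. That count was 0 without week 50 low replicate 1, 2 or 3, without week 72 low replicate 1, 2 or 4 and without the 3 libraries least like the others. In the fatty acid and triglyceride synthesis list 9 of 32 were lower over the list alone, with SCD at -3.72 ± 0.93 and ACACA, which makes malonyl-CoA, at -1.08 ± 0.30 (camera adjusted p = 2.96e-05, adjusted p = 0.124 with an estimated correlation). This count was 5 without week 50 low replicate 1, 4 without week 72 low replicate 4, and 0 without week 50 low replicate 2 or 4 or week 72 low replicate 1. It was 1 after median-ratio scaling and 5 without the 3 libraries least like the others. Of 15 yolk members 5 were lower over the list alone, VTG1 (-5.62 ± 1.53), VTG2 (-3.60 ± 0.92), VTG3 (-4.52 ± 1.09), APOV1 (-3.27 ± 0.98) and RBP (-2.81 ± 0.92), 3 without week 72 low replicate 4, while the list did not pass camera (adjusted p = 0.104).

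Endothelial markers were higher in week 72 low, with VWF (1.13 ± 0.26), FLT1 (0.79 ± 0.24) and KDR (0.71 ± 0.23) passing over the list alone, 3 of 26 (camera adjusted p = 1.15e-09, adjusted p = 0.0843 with an estimated correlation). Their number was 1 without week 50 low replicate 1 or 2 or week 72 low replicate 2, 6 without week 50 low replicate 3 and 0 without week 72 low replicate 1. T or NK cell markers passed camera as lower (median -0.72, adjusted p = 0.524 with an estimated correlation, exact permutation p = 0.171), as did B or plasma cell markers (median -1.73, adjusted p = 0.175 with an estimated correlation, exact permutation p = 0.257), where POU2AF1, MZB1 and IRF4 passed over the list alone, 3 of 6. That number was 1 without week 50 low replicate 1 or 3 or week 72 low replicate 1, 5 without week 50 low replicate 2 or 4 or week 72 low replicate 3, and 0 without the 3 libraries least like the others. Glycolysis and gluconeogenesis passed camera as higher with a mean of 0.08 and a median of -0.02, which was 0.07 after median-ratio scaling (adjusted p = 0.524 with an estimated correlation).

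FABP5, a fatty acid carrier (1.53 ± 0.28), LOXL3 (0.995 ± 0.20) and CREBL2 (0.89 ± 0.19) had the smallest p as higher in week 72 low but were not called (limma adjusted p = 0.052, 0.067 and 0.07). At an unadjusted p under 0.05, 247 genes were higher and 845 lower. After median-ratio scaling limma called 3 genes as higher and 8 as lower, including all 5 called on the deposited scale, and 489 were higher and 651 lower unadjusted. The number called was 12 with the replicate block, 0 with no filter or only the groups compared in the fit, 0 without week 50 low replicate 1, 2 or 3 or week 72 low replicate 1, 2 or 4, 0 without the 3 libraries least like the others, 26 without week 50 low replicate 4, and 95 (12 higher and 83 lower) without week 72 low replicate 3.

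In high layers, cell cycle and T or NK cell lists passed camera as lower at week 72 than at week 50 and the erythroid list as higher, with exact permutation p = 0.114, 0.0571 and 0.0286 for their means. AURKB, a mitotic kinase (-1.02 ± 0.31), and PLK1 (-1.39 ± 0.45) were among the cell cycle members with the smallest p (camera adjusted p = 9.09e-16, median -0.74, adjusted p = 0.549 with an estimated correlation), with 0 of 37 passing over the list alone. CD3E, a T cell receptor chain, had 26.3 ± 10.2 TPM against 56.3 ± 12.8 TPM (SD, n = 4), and CD8BP differed by -1.45 ± 0.45 (camera adjusted p = 1.33e-08, adjusted p = 0.549 with an estimated correlation). The globin genes HBBA (1.78 ± 0.60), HBAD (1.89 ± 0.67) and HBA1 (1.498 ± 0.55) passed over the erythroid list alone, 3 of 9, and 0 over all genes, with a camera adjusted p = 7.06e-08 and adjusted p = 0.268 with an estimated correlation. That count was 0 without week 50 high replicate 1, 2 or 3 or any 1 of the week 72 high libraries. Yolk precursors passed camera as higher (median 0.34, adjusted p = 0.00528, adjusted p = 0.549 with an estimated correlation), with VTG1 at 0.60 ± 1.53, VTG2 at 0.34 ± 0.92 and APOV1 at 0.30 ± 0.98. IDH3A (1.01 ± 0.26) and GNB3 (1.18 ± 0.30) had the smallest p as higher and SPON2 (-2.57 ± 0.59) and PTMA (-0.77 ± 0.18) as lower.

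For week 72 against week 50 in high layers, limma called 0 of 12808 genes and 588 had an unadjusted p under 0.05, 75 higher and 513 lower, or 199 and 321 after median-ratio scaling. The median of all genes was -0.10, and 0.02 after scaling. The number called was 1 without week 72 high replicate 1. Camera called 6 lists, 13 without week 72 high replicate 2 and 11 without replicate 3.

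Against week 32, week 50 high livers had higher values of T or NK cell markers: 14 of 23 passed adjusted over the list alone and 0 over all genes. CD3D (1.46 ± 0.36), CD3E (1.36 ± 0.36), CD8BP (1.68 ± 0.45) and CD6 (1.39 ± 0.39) led the list, and CD3E was 20.9 ± 2.42 TPM at week 32. Camera gave an adjusted p = 1.02e-10 (median 0.82, or 0.67 after median-ratio scaling), with adjusted p = 0.64 with an estimated correlation and an exact permutation p = 0.0286. The count was 9 without week 32 replicate 2 or week 50 high replicate 3. Interferon response (median 0.74) and cholesterol synthesis (0.68) were higher and extracellular matrix and stellate cell markers (-0.26) lower by camera, with adjusted p = 0.7, 0.7 and 0.64 with an estimated correlation. Endothelial markers passed as lower with a median of -0.09 and a mean of 0.00 (adjusted p = 0.7 with an estimated correlation). PFKFB1, a regulator of glycolytic flux (1.04 ± 0.26), passed over its list alone, 1 of 27. VTG1 (-0.89 ± 1.53), VTG2 (-0.45 ± 0.92), VTG3 (-0.85 ± 1.09), APOV1 (-0.34 ± 0.98) and APOB (-0.62 ± 0.72) did not pass.

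ABHD11 (1.03 ± 0.19), PSMA5 (0.75 ± 0.17) and SSH3 (0.97 ± 0.22) had the smallest p as higher in week 50 high against week 32, and PLSCR1 (-2.19 ± 0.54), SRRL (-0.83 ± 0.21) and PSD3 (-0.85 ± 0.22) as lower. Limma called 0 of 12808 genes and 1284 had an unadjusted p under 0.05, 1088 higher and 196 lower. The median of all genes was 0.13, and -0.01 after median-ratio scaling, when 603 were higher and 501 lower. Camera called 10 lists, 6 without week 32 replicate 3.

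In week 72 high livers extracellular matrix and stellate cell markers passed camera as lower than at week 32 (median -0.51, mean -0.49 ± 0.21, exact permutation p = 0.0857). COL4A2, a basement membrane collagen (-0.80 ± 0.23), LOX, which crosslinks collagen (-1.40 ± 0.43), and PDGFRB (-0.73 ± 0.24) were among them, with 0 of 34 passing over the list alone, a camera adjusted p = 3.23e-13 and adjusted p = 0.539 with an estimated correlation. Erythroid markers were higher (median 0.66, adjusted p = 0.691 with an estimated correlation), with HBBA at 318 ± 60.3 against 109 ± 32.6 TPM (SD, n = 4). The exact permutation p of the erythroid list mean was 0.0286, or 0.295 adjusted over lists. Limma called 1 gene, LOC107049678, which rose by 2.08 ± 0.27 (adjusted p = 0.00414) from 0.210 ± 0.256 TPM at week 32, with all 4 week 72 high libraries above all 4 of week 32. The call was lost with a pseudocount of 0.1 (adjusted p = 0.288), and a filter of 5 TPM left the gene out. Of the symbol-named genes PCDH18 (-1.14 ± 0.22) and TRIM47 (-1.34 ± 0.28) had among the smallest p as lower. VTG1 (-0.29 ± 1.53), VTG2 (-0.11 ± 0.92), VTG3 (-0.39 ± 1.09), APOV1 (-0.04 ± 0.98) and APOB (0.07 ± 0.72) did not pass. At an unadjusted p under 0.05, 374 genes were higher and 294 lower, or 411 and 417 after median-ratio scaling. Camera called 9 lists, 5 without week 32 replicate 2.

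The age differences of high layers from week 32 at weeks 50 and 72 share the week 32 libraries. Across genes their covariance was 0.0852. Simulated unchanged groups that shared a simulated control gave 0.0590 (0.0546 to 0.0646 in 100 draws), a difference of 0.0262. Genes were drawn independently, each with a spread pooled over all groups. The simulated range therefore leaves out correlation between genes and cannot tell this difference from chance. The correlation was 0.634 against a simulated 0.501. With week 32 split into separate pairs in 6 ways the covariance averaged 0.0377 (0.0212 to 0.0469) and the correlation 0.213.

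Week 50 low livers had higher interferon response values than week 32, with 14 of 35 members passing adjusted over the list alone and 0 over all genes. CMPK2 (2.41 ± 0.60), the antiviral gene OASL (3.06 ± 0.87) and IRF7 (1.11 ± 0.30) were among them, with a camera adjusted p = 5.93e-17 (median 1.03), adjusted p = 0.316 with an estimated correlation and an exact permutation p = 0.0286. The count was 0 without week 32 replicate 2 or without the 3 libraries least like the others, 8 without week 32 replicate 1 or week 50 low replicate 1 or 3, 9 without week 32 replicate 4, 7 without week 50 low replicate 2 and 29 without week 50 low replicate 4. Of 20 cholesterol synthesis members 8 were higher over the list alone, among them STARD4 (1.78 ± 0.39) and MVD (1.57 ± 0.37), with camera adjusted p = 1.27e-08 and adjusted p = 0.316 with an estimated correlation, and 5 without week 32 replicate 2 or week 50 low replicate 2. B or plasma cell markers passed for 5 of 6 over the list alone, with IGLL1 at 4.002 ± 1.21 and JCHAIN at 2.79 ± 0.90 (adjusted p = 0.316 with an estimated correlation). Their number was 3 without week 32 replicate 4, and 0 without week 50 low replicate 1 or 3 or without the 3 libraries least like the others. The scores of these markers in week 50 low replicates 1 to 4 were 5.91, 3.15, 6.74 and 3.33.

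T or NK cell markers also passed camera as higher in week 50 low than at week 32 (median 0.60, adjusted p = 0.611 with an estimated correlation, exact permutation p = 0.143) and extracellular matrix and stellate cell markers lower (-0.34, adjusted p = 0.316 with an estimated correlation). BUB1 (1.72 ± 0.45) passed over the cell cycle list alone and THRSPB (2.14 ± 0.39) and SREBF1 (1.07 ± 0.28), regulators of lipid synthesis, over the fatty acid and triglyceride synthesis list alone. AP4M1 (0.78 ± 0.16) and LRRC20 (1.38 ± 0.29) had among the smallest p as higher and SRRL (-0.999 ± 0.21), SH3BP4 (-0.78 ± 0.20) and TSPAN18 (-0.95 ± 0.25) as lower. Differences of yolk precursors from week 32 were -1.55 ± 1.53 for VTG1, -0.86 ± 0.92 for VTG2, -1.21 ± 1.09 for VTG3 and -0.81 ± 0.98 for APOV1. Limma called 0 of 12808 genes, 3 without week 50 low replicate 4, and 1141 had an unadjusted p under 0.05, 861 higher and 280 lower, or 617 and 552 after median-ratio scaling. Camera called 7 lists, 11 without week 32 replicate 2 and 13 without week 50 low replicate 4.

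Week 72 low livers had lower vitellogenin values than week 32 in 3 of 4 libraries. VTG1 (-7.17 ± 1.53), VTG2 (-4.46 ± 0.92), VTG3 (-5.72 ± 1.09), APOV1 (-4.08 ± 0.98) and RBP (-3.19 ± 0.92) were lower and APOA1 (1.86 ± 0.43) and APOA5 (0.92 ± 0.35) higher adjusted over the list alone, 7 of 15, and 0 over all genes with limma. The list passed camera as lower (adjusted p = 0.0278, or 0.0676 with the replicate block, adjusted p = 0.673 with an estimated correlation and exact permutation p = 0.114), with a median of -0.02 and a mean of -1.49 ± 0.41. Cholesterol synthesis was lower for 11 of 20 members over the list alone, among them INSIG1 (-1.51 ± 0.41), with a camera adjusted p = 1.78e-13, adjusted p = 0.66 with an estimated correlation and an exact permutation p = 0.143. That count was 6 without week 32 replicate 1 or 4, 4 without week 32 replicate 3, 2, 4, 17 and 7 without week 72 low replicates 1, 2, 3 and 4, and 1 without the 3 libraries least like the others. In the fatty acid and triglyceride synthesis list 6 of 32 were lower, with SCD at -3.86 ± 0.93, and SREBF1 (0.83 ± 0.28) higher over the list alone (adjusted p = 0.673 with an estimated correlation). HBBA (1.98 ± 0.60), HBA1 (1.76 ± 0.55) and HBAD (2.07 ± 0.67) were higher over the erythroid list alone, 3 of 9 (camera adjusted p = 0.000245, adjusted p = 0.673 with an estimated correlation).

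FABP5 (1.504 ± 0.28), WDR66 (1.48 ± 0.29) and PECR (0.998 ± 0.22) had the smallest p as higher in week 72 low against week 32, and SLC25A22 (-1.32 ± 0.25) among those as lower. Limma called 0 of 12808 genes and 985 had an unadjusted p under 0.05, 422 higher and 563 lower. The number called was 1 without week 32 replicate 2 and 71 (14 higher and 57 lower) without week 72 low replicate 3. Camera called 8 lists, 5 without week 72 low replicate 2.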

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

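All weighing of the 3 patterns below rests on tests chosen after the result was seen, except the relation of the cholesterol synthesis score to VTG2, and the regroupings of the libraries were also read after their counts had been seen.

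Low vitellogenin and APOV1 in the week 72 low libraries was the first pattern. A smaller share of hepatocytes was argued against by the 13 hepatocyte markers outside the yolk list, whose median high minus low difference was -0.014 (SD 0.55 over markers), far from the 4.35 of VTG2. Scaling between libraries was argued against by the VTG2 difference of 4.30 after median-ratio scaling. A single mislabelled library was argued against as the cause of the low values, since the VTG2 difference was at least 3.40 ± 0.83 whichever week 72 low library was left out, while a wrong label stays open for replicate 3 alone, which had VTG2 at 95.5% of the week 72 high mean, since the labels hold no second mark of laying. A difference between hens that stopped and hens that still produced yolk precursors may also account for it, and the labels give no measure of laying per library to test it.

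Low cholesterol synthesis transcripts in week 72 low against week 50 low was the second. The median of the list was -2.32 with all libraries, -2.04 without the 3 libraries least like the others and -2.18 after median-ratio scaling, so neither those libraries nor scaling accounts for the whole difference. Part of it lies in week 50 low, whose list score of 7.09 ± 0.28 was the highest of the 5 groups, against 6.11 ± 0.30 at week 32 (SD, n = 4). Against week 32, the mean difference of the list in week 72 low was -1.09 ± 0.38 (SE). Its exact permutation p was 0.143, and camera with an estimated correlation gave an adjusted p = 0.66. Over the 16 libraries of the other 4 groups, centred by group, the list score varied with VTG2 with Pearson r = 0.57 (permutation p = 0.0409, adjusted p = 0.0819 over 8 relations; Spearman rho = 0.574, permutation p = 0.0384), and r was 0.49 without the 2 most extreme libraries. This misses the threshold after adjustment. Whether both quantities vary together between libraries therefore cannot be told apart from chance with 16 libraries. Age by itself would lower the list score of week 72 high too. That score was 6.50 ± 0.31 (SD, n = 4), against 6.76 ± 0.42 in week 50 high. It was 5.03 ± 1.01 in week 72 low, where replicate 3 had 6.50. These values argue against age alone for the whole difference. Age combined with low laying stays open, since what made the groups differ was not tested.

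High T or NK cell markers in week 50 high against week 32 was the third. A smaller share of hepatocytes would raise the markers of other cell types alike, but the extracellular matrix and stellate cell list had a median of -0.26 and the endothelial list -0.09, against 0.82 for the T or NK list. Without the 3 libraries least like the others, 18 members passed with an adjustment over the list alone. Of those libraries only week 50 high replicate 1 is in this comparison. Its T or NK score of 2.74 was the lowest of its group (others 3.29 to 3.56). Leaving it out was bound to raise the difference, so this count cannot test those libraries as a cause. More blood left in the tissue would raise erythroid markers too, but the median of these 9 was -0.20 (SD 0.71 over markers). B or plasma cell and macrophage or Kupffer cell markers had medians of 0.45 and 0.44, neither list passing camera (adjusted p = 0.853 and 0.30). A larger number of T or NK cells in these livers remains a hypothesis that was not tested. The T or NK list did not pass camera with an estimated correlation, and the labels record nothing of immune status.

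Among 150 sets of 4 libraries examined, 12 held a library far from the other 3, where chance alone gives 7.5. In week 50 high, replicate 1 had APOB at 272 TPM (others 1894 to 2287), MTTP at 32.0 TPM (others 82.1 to 95.9) and an endothelial score of 2.997 (others 3.27 to 3.31). Replicate 3 of that group had a B or plasma cell score of 2.66 (others 3.54 to 3.65). In week 50 low, replicate 2 had TTR at 2776 TPM (others 3921 to 4144), replicate 3 had a yolk precursor score of 9.46 (others 10.25 to 10.41), and replicate 4 had MVD at 117 TPM (others 49.8 to 55.8) and an interferon score of 5.50 (others 6.31 to 6.46). Replicate 4 of week 72 high had APOV1 at 73252 TPM (others 42274 to 43898) and replicate 3 of week 72 low had VTG3 at 2230 TPM (others 8.54 to 23.1). At week 32, replicate 3 had MVD at 29.9 TPM (others 18.5 to 19.5) and replicate 4 a T or NK cell score of 2.60 (others 2.27 to 2.27). Scores are means of log2(TPM + 1) over the members of a list.

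The difference of the high minus low effect between ages, week 72 minus week 50, passed camera for 11 lists. Their medians were 2.08 for cholesterol synthesis, 0.72 for interferon response, 0.50 for fatty acid and triglyceride synthesis, 0.18 for ribosomal proteins, 0.18 for yolk precursors, 1.55 for B or plasma cells, 0.33 for cell cycle, 0.70 for erythroid cells, -0.29 for endothelial cells, -0.24 for extracellular matrix and stellate cells and -0.17 for estrogen and nuclear receptors. With an estimated correlation only cholesterol synthesis passed (adjusted p = 0.0328), and 24 of 100 regroupings gave 11 or more such lists, the highest other 16.

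Regroupings of the libraries excluded chance for no count. For genes called, 4 of the 35 splits gave as many as the real 1 in week 72 high against low (highest other 125), 4 of 35 as many as the real 1 in week 72 high against week 32 (highest other 1), 4 of 35 as many as the real 5 in week 72 low against week 50 low (highest other 324), and 7 of 100 as many as the real 1 over both ages (highest other 12). For genes at an unadjusted p under 0.05 where none was called, the numbers were 28 of 35 in week 50 high against low (real 380, highest other 2418), 79 of 100 for the difference between ages (304, 1764), 4 of 35 in week 50 high against week 32 (1284, 2164), 7 of 35 in week 72 high against week 50 high (588, 2037), 7 of 35 in week 50 low against week 32 (1141, 2313) and 4 of 35 in week 72 low against week 32 (985, 1182). For lists passing camera they were 20 of 35 in week 50 high against low (real 9, highest other 14), 9 of 35 in week 72 high against low (11, 15), 21 of 100 over both ages (12, 17), 2 of 35 in week 50 high against week 32 (10, 12), 16 of 35 in week 72 high against week 32 (9, 13), 28 of 35 in week 72 high against week 50 high (6, 14), 8 of 35 in week 72 low against week 50 low (14, 17), 27 of 35 in week 50 low against week 32 (7, 18) and 21 of 35 in week 72 low against week 32 (8, 14). Splits that called 324 or 125 genes, far more than the real ones, point to a structure of the samples that the group labels do not follow in full. Each exchanged 1 library of either group, so the group difference can be part of these counts. The split with 125 set week 72 low replicates 1, 2 and 4 and week 72 high replicate 1 against week 72 low replicate 3 and the other high libraries, and so parted replicate 3 from the rest of its group. The split with 324 set week 50 low replicates 1, 2 and 3 and week 72 low replicate 2 against the other 4 libraries. What sets these sides apart was not tested.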

How the results depend on the processing

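The fit without the 3 libraries least like the others, the counts of lists under other settings than the block, the estimated correlation and fry, the counts of list members and the permutation of replicate numbers were tests chosen after seeing the data. Of 220 pairs of a named gene and a comparison, 3685 values under alternatives gave 3470 with the same direction and side of the threshold, 69 weaker, 109 stronger and 37 reversed, the last in 15 pairs. The cause was not tested for any change below. TPM keeps no depth, so counting error in low genes could not be set apart.

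For genes called in week 72 high against low, over both ages, in week 72 high against week 32 and in week 72 low against week 50 low, a pseudocount of 0.1 gave 0, 0, 0 and 19, no filter 0, 2, 3 and 0, and a filter of 5 TPM 0, 0, 0 and 13. Median-ratio scaling gave 11 in the last. Array weights gave 11 in the first and 50 in the last, 79 in week 50 high and 6 in week 50 low against week 32, 10 in week 72 low against week 32 and 3 in week 72 high against week 50 high. Only the groups compared gave 0, 0, 2 and 0, 6 in week 72 high against week 50 high and 1 in week 50 low against week 32. Without the 3 libraries the first, second and last were 0.

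The replicate block left 0 genes in week 72 high against low, 0 over both ages and 12 in week 72 low against week 50 low, 5 lists in week 72 low against week 32, 24 interferon members in week 50 low against week 32, and the yolk median over both ages at 0.19, no longer past the threshold. The samples were not treated as paired, since 0 of 10 group pairs had every correlation over 0.1 (range -0.27 to 0.28). However, 11 of 20 libraries correlated best with their own number, where permuted numbers gave a mean of 5.002 (permutation p = 0.0277), so the data hint at something shared by number.

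The number of lists was 6 over both ages with a filter of 5 TPM and 9 in week 72 low against week 50 low with median-ratio scaling. Array weights gave 10 in week 72 high against week 50 high and 11 in week 50 low against week 32, and 29 interferon members there. Only the groups compared and leaving out the 3 libraries gave 5 in week 72 low against week 32, with yolk medians over both ages of 0.19 and 0.20, no longer past the threshold. With an estimated correlation 1 list held for the difference between ages, 1 in week 72 low against week 50 low and 0 elsewhere, and fry called 2 in week 72 low against week 50 low and 0 elsewhere. Its mixed form, in which members may move either way, called 3 in week 72 high against low, 7 in week 72 low against week 50 low, 6 in week 72 low against week 32 and 0 elsewhere.

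Leaving out single libraries gave 0 to 63 genes in week 72 high against low, 0 to 33 over both ages, 0 to 18 for the difference between ages, 0 to 1 in week 72 high against week 50 high, 0 to 95 in week 72 low against week 50 low, 0 to 3 in week 50 low and 0 to 71 in week 72 low against week 32. Lists ranged from 6 to 12 in week 50 high, 5 to 11 in week 72 high, 7 to 13 in week 50 low and 5 to 8 in week 72 low against week 32, and 5 to 13 in week 72 high against week 50 high. Yolk medians ranged from -0.056 to 0.27 in week 50 high against low, negative without week 50 low replicate 3, and 0.12 to 0.33 over both ages.

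Reversed genes, none called, in week 50 high against low were RBP (-0.038 with median-ratio scaling, -0.28 with array weights, -0.22 without the 3 libraries, -0.13 to 0.28 leaving out 1), VTG1 (-0.040 without the 3, -0.074 to 1.09), VTG3 (-0.013 without the 3), APOB (-0.48 to 0.85) and MTTP (-0.077 to 0.44). In week 72 high against low they were TF (-0.0070 with array weights, -0.0011 to 0.34), MTTP (-0.029 to 0.19), RBP4 (-0.0014 to 0.47), APOA5 (-0.41 to 0.035) and APOA4 (-0.12 to 0.71). APOB in week 50 high against week 32 was 0.12 without the 3 (-0.95 to 0.12 leaving out 1), and in week 72 high against week 32 -0.039 with array weights (-0.27 to 0.30), with VTG2 at -0.21 to 0.00081 and APOV1 at -0.23 to 0.073. VTG3 in week 72 high against week 50 high ranged from -0.073 to 0.74.

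Counts of members passing adjusted over the list alone moved as follows. Only the groups compared gave 27 for interferon response (14 with all groups), 13 for cholesterol synthesis (8) and 3 for B or plasma cell markers (5) in week 50 low against week 32, 1 for cholesterol synthesis (11) in week 72 low against week 32, and 0 for fatty acid and triglyceride synthesis (9), 0 for yolk precursors (5), 1 for B or plasma cell (3) and 1 for endothelial markers (3) in week 72 low against week 50 low. It also gave 3 yolk precursors (5) and 1 fatty acid and triglyceride synthesis member (5) in week 72 high against low, 0 for cholesterol synthesis (4) over both ages, 1 for B or plasma cell markers (2) in week 50 high against low and 5 for erythroid markers (3) in week 72 high against week 50 high. No filter gave 0 for cholesterol synthesis over both ages, 3 for fatty acid and triglyceride synthesis and 2 for interferon response (18) in week 72 low against week 50 low, 0 for the erythroid markers, 9 for B or plasma cell markers in week 50 low against week 32 and 1 in week 50 high against low, where a pseudocount of 0.1 and array weights also gave 1. A filter of 5 TPM gave 16 cell cycle members (27) in week 72 low against week 50 low, where median-ratio scaling gave 1 for fatty acid and triglyceride synthesis and 5 for endothelial markers. Array weights gave 5 endothelial and 5 B or plasma cell members there, 14 for cholesterol synthesis in week 50 low against week 32, 10 over both ages and 9 for fatty acid and triglyceride synthesis in week 72 high against low. The replicate block gave 0 for cholesterol synthesis over both ages, 1 for endothelial markers in week 72 low against week 50 low and 1 for B or plasma cell markers in week 50 high against low.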

Other observations

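The tests of relations to VTG2 were set before their values were seen, while TCN2, FAM20CL, WFDC8 and ENPP7 entered those tests because of their values in the week 72 comparison.

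A few genes that handle circulating lipoproteins, but not their list, were higher in week 72 low than at week 32. LCAT, which esterifies cholesterol on circulating lipoproteins, was 2.25 ± 0.51 higher on the log2 scale and CETP, which moves cholesteryl esters between lipoproteins, 2.80 ± 0.69 higher (SE, 4 libraries per group), both passing with an adjustment over the lipoprotein handling list alone, where APOA1, LCAT, CETP and LPL (4 of 26) passed as higher and APOV1 (1) as lower, while 0 passed over all genes with limma. The list itself did not pass camera (adjusted p = 0.0967). LDHB, a lactate dehydrogenase subunit, was 2.08 ± 0.55 higher and led 3 of 27 glycolysis and gluconeogenesis members passing over the list alone (camera adjusted p = 0.0471, or 0.0676 with the replicate block, adjusted p = 0.673 with an estimated correlation). Against week 50 low the fibrinogen chain genes FGA, FGB and FGG, clotting factors made by hepatocytes, had differences of 1.06 ± 0.37, 0.93 ± 0.37 and 0.99 ± 0.40, none passing over its list.

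The remaining lists had no member passing over all genes in any comparison. Camera called fatty acid oxidation and ketogenesis in 4 comparisons (medians -0.10 to 0.31), immediate early and heat shock genes in 5 (-0.36 to 0.05), ribosomal proteins in 7 (-0.22 to 0.18), thrombocyte markers in 3 (-0.32 to 0.14), cholangiocyte markers in 2 (-0.28 to 0.13), estrogen and nuclear receptors in 2 (-0.23 to 0.13), and 1 each for endoplasmic reticulum protein folding (-0.02 to 0.14), acute phase and inflammation (-0.18 to 0.18), the growth hormone and IGF axis (-0.21 to 0.11), the circadian clock (-0.24 to 0.37) and hepatocyte markers (-0.27 to 0.18). None of these calls held with an estimated correlation, where the smallest adjusted p among these lists was 0.124, for hepatocyte markers. Bile acid synthesis and transport (medians -0.10 to 0.28), amino acid and one-carbon metabolism (-0.26 to 0.09), antioxidant defence and detoxification (-0.18 to 0.15), macrophage or Kupffer cell (-0.45 to 0.44), heterophil (-0.26 to 0.22) and adipocyte markers (-0.18 to 0.30) were called in 0 of 10 comparisons, although up to 4 of 12 adipocyte members passed adjusted over the list alone. The pancreatic acinar and skeletal muscle lists had 3 tested members each and were not tested, with medians of -0.42 to 0.26 and -0.34 to 0.36.

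A hypothesis formed from the week 72 low libraries was that a set of secreted protein transcripts varies with VTG2 between libraries in general. It was tested in the 16 libraries of the other 4 groups, centred by group, on log2(TPM + 1), with 8 relations and 100000 permutations within groups. RBP, the riboflavin-binding protein gene, had Pearson r = 0.87 (permutation p = 0.00017, adjusted p = 0.00136; rho = 0.859, permutation p = 0.00073) and r = 0.87 without the 2 most extreme libraries. APOV1 had r = 0.81 (permutation p = 0.00577, adjusted p = 0.0154; rho = 0.715, permutation p = 0.00702) and 0.57 without them. FAM20CL, named for its likeness to a kinase of secreted proteins, had r = 0.89 (permutation p = 0.00147, adjusted p = 0.00588; rho = 0.744, permutation p = 0.0042) and 0.73 without them. The relations of RBP and APOV1 are consistent with shared variation of yolk precursor transcripts between libraries, although the libraries have unequal scaling and composition, which was not removed. FAM20CL is not in the yolk precursor list.

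The other relations did not pass. Pearson r was 0.40 for the fatty acid and triglyceride synthesis score (permutation p = 0.214, adjusted p = 0.285; rho = 0.379, permutation p = 0.20), 0.23 for TCN2 (0.449, 0.449; rho = 0.235, permutation p = 0.424), 0.38 for WFDC8 (0.125, 0.20; rho = 0.256, permutation p = 0.340) and 0.23 for ENPP7 (0.439, 0.449; rho = 0.165, permutation p = 0.566). Without the 2 most extreme libraries r was 0.30, 0.13, 0.21 and 0.08. The relations of these 4 measures to VTG2 therefore remain undecided in 16 libraries.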
